A study of Mus musculus with 2 samples.

How the data were processed

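Single-cell RNA sequencing of dissociated mouse retina at postnatal day 7 (P7) was compared between a control library (Mettl14 fl/fl or fl/wt, without Cre) and a Mettl14-cKO library (Mettl14 fl/fl with a transgene that expresses Cre recombinase in retinal progenitors). Each genotype was represented by 1 library. The labels do not say how many animals or retinas each library pooled, and they do not give the sex of the animals or a sequencing batch. Per the labels, retinas were dissociated with papain and libraries were made with the 10x Genomics Chromium 3' kit v3.1, which tags the 3' end of polyadenylated RNA with a cell barcode and a unique molecular identifier (UMI).

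The deposited matrices hold UMI counts per gene and barcode, without normalization. Per the file headers and the submitters' processing notes, the authors made them with Cell Ranger 6.1.1 on the mouse build mm10; the values are whole numbers over 32285 genes, and the lowest total of a barcode was 500 UMIs in both libraries. The control library held 13287 barcodes with 55921787 UMIs (median 3062 per barcode), and the Mettl14-cKO library 15319 barcodes with 59856468 UMIs (median 2887). Reads, intronic reads and empty droplets were not analysed here, so free RNA could be gauged only from transcripts found in cell classes that should lack them. In 3' data the counts report the end of a transcript and not its length, and a gene whose deleted exons lie far from the tag can still be counted.

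Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 11361 control and 13480 Mettl14-cKO barcodes. Doublets were called in each library with Scrublet (scanpy 1.11.5) at an expected rate of 0.8% per 1000 barcodes. It marked 7.09% of control and 10.8% of Mettl14-cKO cells at its automatic threshold, and these were removed. The remaining 10556 control and 12018 Mettl14-cKO cells held 49095764 and 49375041 UMIs. Doublets of cells of the same type are not found by this method.

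Both libraries were clustered jointly and without batch correction: counts per 10000 on a log scale, 2000 variable genes, 30 principal components, 20 nearest neighbours, a shared-neighbour graph and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). No cell annotation was among the files, so each of the 29 clusters was named, as "X-like", from 158 marker genes of 16 cell types fixed before the data were examined. A marker counted when its level was at least 2-fold that in all other cells and it was detected in at least 10% of the cells of the cluster. A name needed at least 3 such markers, and the 10 leading genes could not hold more markers of another type. Clusters 3 and 8 did not meet this and are given by number. These rebuilt names may differ from names given elsewhere.

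UMIs were summed per library and class and scaled to a total of 1000000 (CPM). Since each genotype has 1 library, no test was made, no p-value is given, and cells were not treated as replicates. Levels carry exact 95% Poisson intervals, ratios the exact conditional interval, and shares of cells exact Clopper-Pearson 95% intervals. All of these cover counting error only and leave out variation between animals and between preparations. Ratios needed at least 30 UMIs over both libraries. With 0 UMIs in a library the fold was computed against a floor of 3 counts in that class and is named as such. Values written as log2 are Mettl14-cKO over control throughout.

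Of 19 gene lists fixed before the data were examined, the 18 reported here were m6A writers, m6A readers and erasers, S phase, G2 and M phase, cell cycle exit, the Notch pathway, progenitor transcription factors, phototransduction and outer segment, photoreceptor transcription factors, synapse, Müller glia maturation, reactive glia, p53 targets, the integrated stress and unfolded protein response, the interferon response, dissociation and immediate early genes, hypoxia and glycolysis, and X-inactivation and Y-linked genes. A member counted as higher or lower when its ratio was 1.25-fold or more from 1 and the Poisson intervals of both levels did not overlap. The median log2 ratio of a list is given as a percentile among 10000 random lists of the same size matched on expression; this describes these 2 libraries and is not a test of genotype. Some genes stand in more than 1 list, Cdkn1a among them. Some genes with ratios among the highest or lowest, and some list members, are not described here.

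Genes were named by a rule fixed beforehand: Mettl14 in every class; over all kept cells the 12 highest and 12 lowest ratios among genes with at least 200 UMIs; in each class with at least 200 cells in both libraries the 8 highest and 8 lowest among genes with at least 100 UMIs, found in at least 10% of the cells of 1 library, with intervals that do not overlap; and the members of each list with the largest ratios among those with at least 100 UMIs. Mitochondrial, ribosomal protein and haemoglobin genes, unnamed gene models and markers of other classes were left out of the ranking. Genes outside this rule are said to be so.

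Shares of cells with a UMI and cell cycle phase were compared with each cell thinned to 1500 UMIs, and shallower cells were left out. S and G2/M scores followed the usual gene-set scoring against matched genes. The matched genes were chosen in each library apart, so the zero point of a score may differ between the libraries. The steps from sums to calls were tested on simulated counts that held Poisson counting error only, without variation between cells, animals or preparations. Genes set apart were drawn from those with more UMIs than the minimum for a ratio. The rates that follow therefore check the calculation and are not error rates of the calls reported here. Genes set 2-fold apart were recovered in 99.0% of cases in a simulated rod-like class, 95.0% in a Müller glia-like, 97.0% in a bipolar-like, 100% in an amacrine-like and 99.0% in a neurogenic progenitor-like class. Genes set 1.5-fold apart were recovered in 87.0%, 78.0%, 89.0%, 79.0% and 74.0% of cases in the same order. Of genes set equal, 0.270%, 0.351%, 0.343%, 0.367% and 0.602% were called.

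The alternatives were a looser cell filter (200 genes, 500 UMIs, 25% mitochondrial), a stricter one (1000 genes, 2000 UMIs, 10%), no doublet removal, Leiden resolutions 0.5 and 2, each library clustered alone, variable genes without the S phase and G2 and M phase lists, median-ratio size factors, the mean of per-cell counts per 10000, thinning each cell to 1500 UMIs, minima of 100 and 10 UMIs for lists, and unthinned cells or 2500 UMIs for phases. Size factors for the gene lists were added after seeing the data. Gene positions and exon numbers came from the GENCODE annotation of GRCm38, which may differ from the one used upstream. Numerical work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.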

Results

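To ask how loss of Mettl14, a subunit of the methyltransferase complex that places N6-methyladenosine (m6A) on messenger RNA, alters the postnatal retina, 10556 control and 12018 Mettl14-cKO cells of P7 retina were compared. Median depth was 3385 UMIs and 1773 genes per control cell, and 3076 UMIs and 1657 genes per Mettl14-cKO cell. One library was made per genotype, so every difference below is a difference between these libraries with counting error alone as its interval.

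Mettl14 (ENSMUSG00000028114; chromosome 3, 123368297 to 123386108, minus strand, GRCm38) stood at 27.3 CPM in the control library (95% interval 25.8 to 28.8; 1339 UMIs) and at 14.4 in the Mettl14-cKO library (13.4 to 15.5; 712 UMIs), a ratio of 0.529 (0.482 to 0.579). It was lower in rod-like cells (34.5 against 17.6), cone-like cells (37.7 against 16.8), bipolar-like cells (23.5 against 13.8), amacrine-like cells (18.4 against 10.05), ganglion-like cells (12.04 against 4.19) and neurogenic progenitor-like cells (38.5 against 10.99). In Müller glia-like cells it stood at 23.7 against 18.4, a ratio of 0.779 whose interval of 0.576 to 1.05 includes 1. The interval of the ratio also included 1 in progenitor-like cells (0.590; 0.277 to 1.32), cluster 3 (0.629; 0.385 to 1.07) and cluster 8 (1.02; 0.456 to 2.14). Other classes had too few UMIs for a ratio: astrocyte-like cells held 11 against 8 (22.1 and 10.8 CPM, with intervals that overlap), horizontal-like cells 16 against 5, microglia-like cells 0 against 7, pericyte-like cells 5 against 0 and pigment epithelium-like cells 3 against 0. The labels do not say which exons are floxed, so transcripts that lost them may still carry the 3' end that was counted.

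Several partners of Mettl14 in the writer complex stood higher in the Mettl14-cKO library. Of 9 m6A writers, 5 were higher and 2 lower over all kept cells, with a median log2 ratio of 0.41 (percentile 99.6 of random lists). Rbm15, an RNA-binding subunit that directs the complex to its targets, stood at 15.2 against 40.4 CPM (log2 1.41); its paralog Rbm15b (0.86) and Wtap (0.57), the subunit that anchors the complex in nuclear speckles, were also higher. Mettl3, the catalytic partner of Mettl14, was lower (29.2 against 22.4; log2 -0.38). In amacrine-like cells 6 of the 9 were higher and 1, Mettl14, lower, with a median of 0.56. Among 12 m6A readers and erasers, 5 were higher and none lower, with a median of -0.049 (percentile 45.7). They included Igf2bp1 (log2 2.60; 30 against 183 UMIs) and Igf2bp3 (0.72), RNA-binding proteins of early development, and Ythdf2 (1.08), which brings methylated transcripts to decay.

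**Figure D1:**
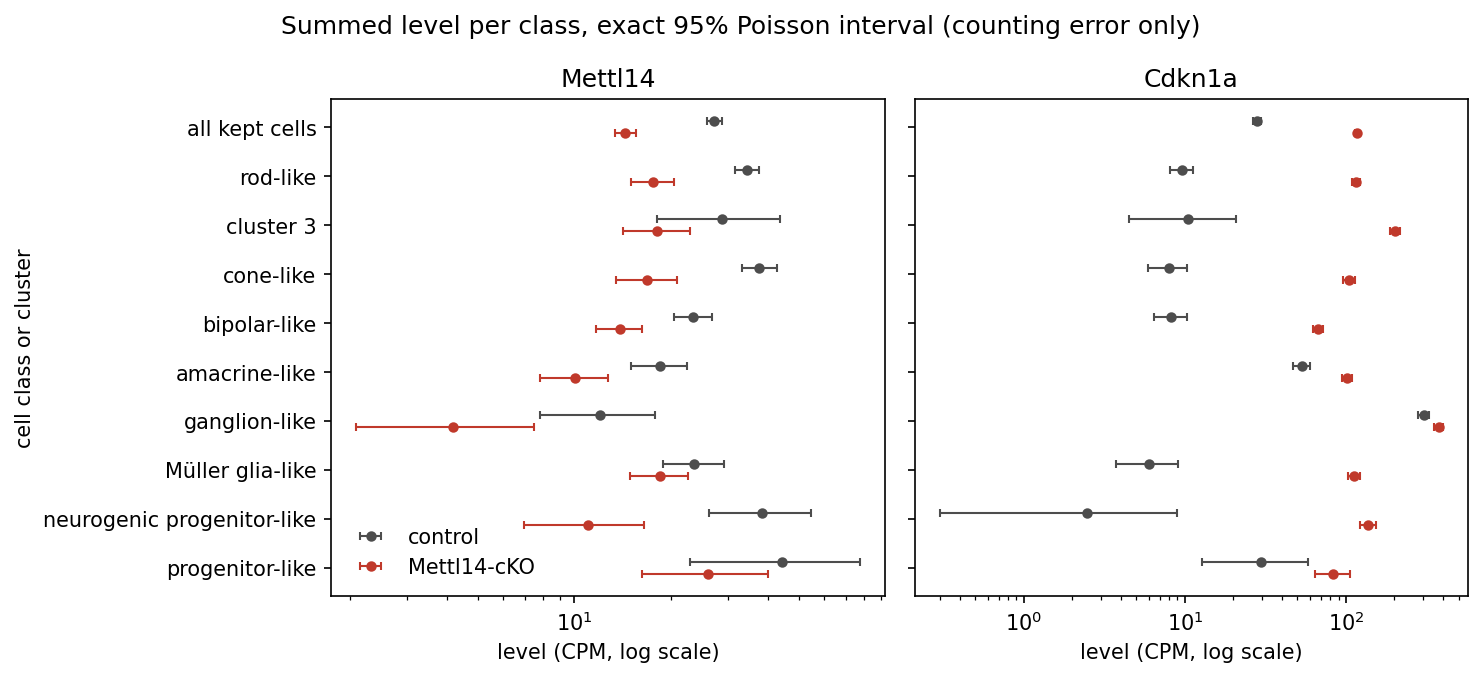
Level of Mettl14 and of Cdkn1a as CPM on a log axis in each cell class of the control (grey) and Mettl14-cKO (red) library. Points are sums over the class and bars are exact 95% Poisson intervals for counting error only; over all kept cells Mettl14 lies at 27.3 and 14.4 and Cdkn1a at 28.0 and 117.

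Rod photoreceptors took a smaller share of the Mettl14-cKO library. Rod-like cells made up 38.3% of control cells (4042 cells; 37.4 to 39.2%) and 18.1% of Mettl14-cKO cells (2176; 17.4 to 18.8%). Cluster 3, led by Insm2, Fabp7, Klhl33 and Gngt2, stayed unnamed because no class had 3 markers there; the closest was the neurogenic progenitor with 2, Btg2 and Insm1. Rod genes were frequent in it as well. At 1500 UMIs Pdc was found in 73.0% of its control and 84.9% of its Mettl14-cKO cells, and Sag in 49.6% and 53.3%. In Müller glia-like cells Pdc was found in 24.3% and 21.2%, and in rod-like cells in 99.97% and 99.95%. Cluster 3 held 3.39% of control and 12.3% of Mettl14-cKO cells. If cluster 3 is counted with the rod-like cells, both together came to 41.7% and 30.4%. The rod-like share moved with the clustering, to 29.95% against 25.2% at Leiden resolution 2 and to 32.8% against 23.2% with each library clustered alone. Cone-like cells were 4.36% (3.98 to 4.76%) and 3.31% (3.00 to 3.65%).

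Müller glia-, amacrine- and ganglion-like cells took larger shares of the Mettl14-cKO library. Müller glia-like cells, the main glia of the retina, were 9.64% of control and 13.0% of Mettl14-cKO cells; amacrine-like interneurons were 11.5% and 16.4%; ganglion-like cells, the output neurons, were 1.62% and 2.29%. Bipolar-like interneurons were 19.7% and 23.5%, a direction that turned with the stricter cell filter, where they were 25.7% and 24.3%. Cluster 8, led by Prdm13, Nhlh2, Ebf1 and Ebf3, held 6.83% and 2.74%. It was closest to amacrine cells, with 5 of their markers (Tfap2c, Gad2, Slc6a9, Slc32a1 and Pax6), but stayed unnamed because its 10 leading genes held a ganglion cell marker, Ebf3, and none of amacrine cells. Counted together, amacrine-like cells and cluster 8 came to 18.3% and 19.2%. Horizontal-like cells were 0.512% and 0.524%. Shares of a library sum to a fixed total, so they do not move independently of each other.

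**Figure D2:**
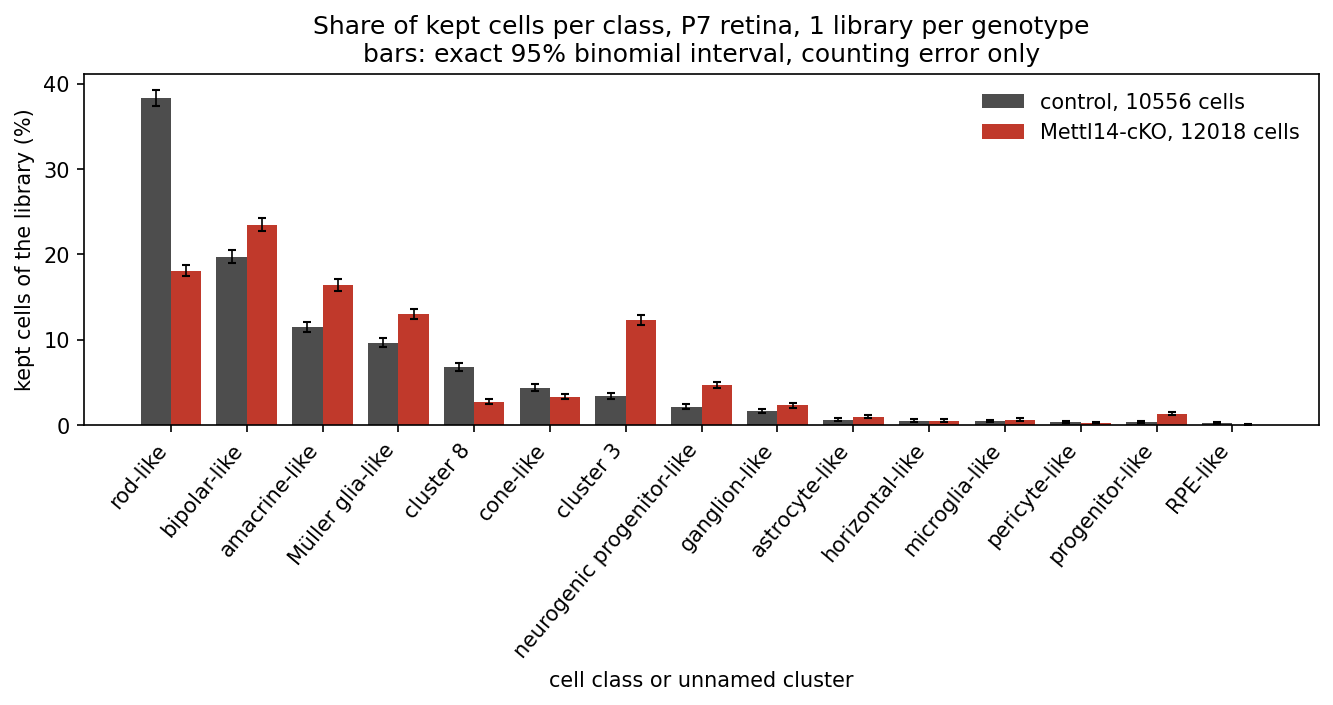
Share of the kept cells (%) in each named class or unnamed cluster of the control (grey) and Mettl14-cKO (red) library, with exact 95% binomial intervals for counting error only. Rod-like cells form the tallest control bar at 38.3%, against 18.1% in the Mettl14-cKO library.

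Cells resembling retinal progenitors were more frequent in the Mettl14-cKO library. Proliferating progenitor-like cells numbered 36 in the control library (0.341%; 0.239 to 0.472%) and 158 in the Mettl14-cKO library (1.31%; 1.12 to 1.53%). Neurogenic progenitor-like cells, led by Neurog2, Gadd45g and Dll1, numbered 224 (2.12%; 1.86 to 2.42%) and 563 (4.68%; 4.31 to 5.08%). Thinned to 1500 UMIs, 33 of 9172 control cells (0.360%) and 153 of 10488 Mettl14-cKO cells (1.46%) had a UMI of at least 2 of Mki67, Top2a, Cdk1, Ube2c and Cenpf; 1384 and 1530 shallower cells were left out, and the unthinned shares were 0.540% and 1.86%. In post-mitotic amacrine-like cells, the background for this measure, 0 of 1104 and 0 of 1640 did, with 95% intervals up to 0.334% and 0.225% (unthinned 0.165% and 0.203%, at median depths of 4119 and 2952 UMIs). The 36 control progenitor-like cells also carried rod transcripts: Gngt1, a rod gene, was found in 47.1% of them at 1500 UMIs, against 27.9% of control neurogenic progenitor-like cells and 11.7% of Mettl14-cKO progenitor-like cells (unthinned 63.9%, 112 of 224 cells and 28.5%).

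Genes of the cell cycle were also higher in the sum of all kept cells. Of 52 genes of G2 and M phase, 35 were higher and 2 lower (median log2 0.71, above all 10000 random lists), led by Mki67 (1.92), Aurkb (1.75) and Cenpf (1.72), with Lbr lower (-0.57). Of 43 S phase genes, 18 were higher and 3 lower (median 0.27, percentile 99.8). Dtl (2.15) and Exo1 (1.96) had the highest ratios, and Nasp (-0.52) and Pcna (-0.45) were lower. The 14 genes of cell cycle exit had 4 higher, 2 lower and a median of -0.14 (percentile 21.2); Cdkn1a (2.07) and Gadd45g (1.06) were higher, Gadd45a (-0.62) and Rb1 (-0.55) lower. Of 20 Notch pathway genes 9 were higher and 1 lower (median 0.32, percentile 99.4). Notch2 (1.42) and Hes1 (1.24), an effector that keeps progenitors undifferentiated, were among the higher, while Jag1 was lower (-0.83). Among 18 progenitor transcription factors 6 were higher, including Hes1 and Lhx2 (1.03), and 2 lower, Id1 (-1.05) and Zfp36l2 (-0.73), with a median of 0.075 (percentile 91.9).

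Within neurogenic progenitor-like cells, 6 of 21 measured S phase genes were higher and none lower (median 0.69), among them Casp8ap2 (1.02) and Usp1 (0.87); restricted to genes with at least 100 UMIs the median was 0.013. Genes of Müller glia maturation were lower there, 8 of 17 against 1 higher (median -0.80, below all random lists), including Crym (-2.04) and Rlbp1 (-1.66), which carries retinoids in glia. The gene with the highest ratio was Cdkn1a (2 against 287 UMIs, log2 5.79, interval 3.92 to 8.84). Zfp992 (0 against 108 UMIs) stood 13.8-fold higher at the floor of 3 counts, with an interval from 11.1-fold upward. Lcmt2 (2.91), Cntnap5a (2.62) and Lsm10 (2.61) followed. The lowest were Sct (-3.55), which encodes the hormone secretin, Id1 (-3.21), an inhibitor of basic helix-loop-helix factors, and the immediate early gene Fos (-2.23). Phase scores called 33.0% of 215 control and 47.5% of 535 Mettl14-cKO cells of this class S (unthinned 31.3% and 56.0%; 9 and 28 cells left out), but they also called 31.9% and 30.3% of post-mitotic amacrine-like cells S, so no cycling is read from them. In progenitor-like cells G2/M calls were 85.3% of 34 and 85.5% of 145 cells, with 2 and 13 left out (unthinned 80.6% and 86.1%).

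Müller glia-like cells of the control and Mettl14-cKO library were placed in separate clusters. Clusters 10 and 26 held 844 and 89 of the 1018 control cells, and cluster 4 held 1540 of the 1559 Mettl14-cKO cells. Genes of Müller glia maturation were lower in the Mettl14-cKO library, 17 of 22 against 2 higher (median -0.89, below all random lists). They included Cyp26a1 (-3.33), which degrades retinoic acid, the water channel Aqp4 (-2.41), and Crym (-1.94), which binds thyroid hormone; Mgst1 (1.13) and Clu (0.47) were higher. Across all kept cells the same list had 8 lower and 5 higher members, with a median of -0.15 (percentile 10.1). The lowest genes of the class were Rgcc (-4.32), Myof (-3.83), the ligand Bmp3 (-3.81), the antagonist of bone morphogenetic proteins Sostdc1 (-3.68), and Npy (-3.67), whose product is a peptide transmitter. Among the highest were Cdkn1a (4.23), Zfp992 (3.67), Zfp758 (2.82) and Lcmt2 (2.63). With 1 library per genotype, a cluster filled mostly by 1 library was not read as a cell state.

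Genes of DNA replication and of the p53 response were higher in these glia. Of 34 measured S phase genes 12 were higher and 1 lower (median 0.70), including Fen1 (1.68) and Cdca7 (1.39). Of 15 p53 targets 8 were higher and 1 lower (median 0.87), both medians lying above all random lists, with Aen (2.01) and Phlda3 (1.97) next to Cdkn1a, and Plk2 lower (-0.78). Other genes were higher there too: 4 of 9 neurogenic progenitor markers with none lower (median 0.63, percentile 99.6), and 54 of 82 ribosomal protein genes with none lower (0.44, above all random lists). Of 11 amacrine markers 4 were higher and 1 lower (0.59, percentile 99.2). At 1500 UMIs the amacrine marker Gad1 was found in 0.557% of control and 1.04% of Mettl14-cKO Müller glia-like cells. In bipolar-like cells it was found in 0.349% and 1.64%, so no expression in glia is read from the amacrine markers. Among 17 Notch pathway genes 7 were higher and 2 lower (median 0.36, percentile 97.8): Notch3 (1.13), Dll1 (1.06) and Notch2 (1.01) against Hes5 (-0.62). Reactive glia genes had 4 of 7 lower and none higher (median -0.58, percentile 0.535), including the intermediate filaments Vim (-0.93) and Nes (-0.58). Immediate early genes, which tissue dissociation induces, had 6 of 15 lower and 1 higher (median -0.60), with Ier2 at -1.78 and Fos at -1.44. Hypoxia and glycolysis genes had 9 of 18 lower and none higher (median -0.53), Eno1 (-0.97) and the lactate transporter Slc16a1 (-0.86) among them. S calls made up 26.2% of 898 control and 37.7% of 1440 Mettl14-cKO cells, and G2/M calls 35.7% and 22.8%. Unthinned, S calls were 23.3% and 36.0% and G2/M calls 34.8% and 24.1%. Thinning left out 120 and 119 cells. No cycling is read from these calls, since S calls were frequent in post-mitotic amacrine-like cells too. Cells with at least 2 of the 5 proliferation genes numbered 1 of 898 (0.111%) and 12 of 1440 (0.833%; 0.431 to 1.45%; unthinned 0.589% and 1.99%).

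In rod-like cells, held by clusters 0 and 1 in the control library (2003 and 1982 of 4042 cells) and by cluster 2 in the Mettl14-cKO library (1963 of 2176), phototransduction genes moved in both directions. Of 26, 4 were higher and 8 lower (median -0.064, percentile 27.0). Gnat1, the rod transducin alpha subunit, was higher (1.07), as was Rp1 (0.74), a protein of the outer segment axoneme; Gngt1 (-0.92) and Pde6b (-0.88) were lower. Photoreceptor transcription factors had 1 higher, Rxrg (1.82), a retinoid receptor known from cones, and 4 of 14 lower, including Prdm1 (-0.64) and Crx (-0.33; median -0.18, percentile 5.27). Synapse genes had 7 of 26 lower and 2 higher (median -0.22, percentile 1.30), with Cabp4 (-0.87) and the vesicular glutamate transporter Slc17a7 (-0.62) lower and Nrxn3 (0.35) higher. Of 16 p53 targets 6 were higher and 2 lower (median 0.15, percentile 93.9), led by Cdkn1a (3.59) and Phlda3 (3.29). Among the highest genes were Insm2 (2.80), Gdf11 (2.79) and Lrtm2 (2.79). Among the lowest were Dynlrb2 (-2.88), a dynein light chain, Aldoc (-2.29), Ccdc39 (-1.97) and Pcdh15 (-1.76).

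In cluster 3 more phototransduction genes were higher than lower: 11 of 24 were higher and 2 lower (median 0.53, above all random lists), with Rp1 (2.09) and Pde6g (1.33) higher and Pde6b (-0.54) lower. Cdkn1a stood at 10.5 against 202 CPM (8 against 779 UMIs; log2 4.27), and 4 of 15 p53 targets were higher and 2 lower (median 0.38, percentile 99.2), Bax (0.95) and Sesn1 (-1.04) among them. Gngt1 was found in 46.3% of control and 46.9% of Mettl14-cKO cells of this cluster at 1500 UMIs, where rod-like cells had 98.6% and 97.3% (unthinned 58.4% and 56.7%, 98.1% and 98.7%).

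Cone-like cells had several of the same genes at both ends. Zfp992 (3.74), Cdkn1a (3.71), Insm2 (3.30) and Lrtm2 (3.07) had ratios among the highest, and Dynlrb2 (-4.01), Myo7a (-2.48), Trim36 (-2.48) and the middle-wavelength opsin Opn1mw (-2.24), itself a cone marker, among the lowest. Phototransduction genes had 3 of 26 higher and 11 lower (median -0.18, percentile 1.43), Gnat1 (0.98) and Guca1b (0.87) against Pde6b (-1.02). Of 15 p53 targets 4 were higher and 2 lower (median 0.34, percentile 99.8), including Aen (1.45). Gngt1, a rod gene, stood at 6493 and 3686 CPM in the cone-like cluster. In rod-like cells Gngt1 stood at 64.5 and 34.0 UMIs per 10000 (unthinned), about the same level in each library. Ratios of rod genes in the cone-like cluster, and of genes it shares with rod-like cells, can therefore come from rod RNA. No change in cones is read from them.

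Over all kept cells the photoreceptor lists were lower together with the rod share. Phototransduction and outer segment genes had 20 of 26 lower and 1, Gnat1 (0.48), higher (median -0.57), with Pde6b at -1.45 and Gngt1 at -1.43. Photoreceptor transcription factors had 10 of 14 lower and 2 higher (median -0.59), Samd11 (-0.89) against Rxrg (0.99). Synapse genes had 18 of 27 lower and 2 higher (median -0.58), Cabp4 (-1.28) and Slc17a7 (-1.12) against Bsn (0.34). All 3 medians lay below every random list.

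Summed over all bipolar-like cells, genes for synaptic transmission and glycolysis stood lower in the Mettl14-cKO library. Ribosomal protein transcripts made up 11.3% of UMIs in this class in the control and 14.4% in the Mettl14-cKO library, and mitochondrial ones 3.87% and 2.68%. Synapse genes had 15 of 26 lower and 1 higher (median -0.56, below all random lists), with the ribbon synapse calcium channel Cacna1f (-2.71), Rgs11 (-2.27) and Gnb3 (-1.48), both of the light-response cascade of ON bipolar cells, lower. Hypoxia and glycolysis genes had 14 of 17 lower and none higher (median -0.76), led by Aldoa (-1.23) and Eno1 (-1.13). Progenitor transcription factors had 8 of 18 higher and 3 lower (median 0.46, percentile 99.9): Lhx2 (1.57) and Rax (1.10) against Nfia (-1.76). Hes1 had the ratio 1.81, but its 9.03 CPM in Mettl14-cKO bipolar-like cells matched the 8.78 and 8.76 CPM in rod- and amacrine-like ones, so no expression in bipolar cells is read from it. The lowest genes were Gng13 (-4.00) and Cabp2 (-2.95), which also served as bipolar markers, with Otor (-3.24), Lhx3 (-2.98) and Apoa2 (-2.90). The highest were Zfp992 (4.79), Cdkn1a (3.03), Zfp942 (3.00) and Zfp758 (2.83). Of 15 p53 targets 4 were higher and 3 lower (median -0.042, percentile 47.9). Clusters of bipolar-like cells differed in size. Clusters 9 and 12, led by Vsx1 and by Pcp2 and Gng13, held 5.78% and 5.41% of control cells against 2.22% and 2.21% of Mettl14-cKO cells. Both had Grm6 among their markers, as did cluster 5, which held 5.13% and 6.21%. Clusters 7 and 13, with Grik1 and without Grm6 among their markers, held 1.22% and 2.18% against 7.95% and 4.92%. Ratios of the class pool these clusters, so lower levels per cell cannot be told apart from a changed mix of clusters.

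In amacrine-like cells the zinc finger genes Zfp992 (2.56), Zfp942 (2.31) and Zfp758 (2.09) had high ratios next to Lcmt2 (2.16) and Abcd4 (1.996). Rnf152 (-2.35), the transcription factor Prox1 (-1.88) and Ndnf (-1.87) were lowest. Clusters of amacrine-like cells differed in size: cluster 19, led by Actc1, Ccsap and Unc13d, held 157 of the 1214 control and 43 of the 1974 Mettl14-cKO cells, and cluster 16, led by C1ql2 and Ralyl, held 123 and 427. Synapse genes had 10 of 23 lower and 2 higher (median -0.19, percentile 2.91), with Cplx3, a complexin of some amacrine cells, at -1.78. Markers of other classes were lower there as well: 11 of 13 rod markers with none higher (median -0.73), 14 of 24 phototransduction genes with none higher (-0.65), both medians below all random lists, and 6 of 11 bipolar markers with 3 higher (-0.64). Cdkn1a stood at 53.1 against 102 CPM (log2 0.94), and 3 of 15 p53 targets were higher and 1 lower (median 0.096, percentile 58.7). In ganglion-like cells Cdkn1a already stood at 305 CPM in the control library and at 377 in the Mettl14-cKO library (log2 0.31), and none of 13 p53 targets was higher or lower (median -0.21, percentile 3.01). Of 20 synapse genes in ganglion-like cells 3 were lower and 1 higher (median -0.13, percentile 3.60), Snap25 (-0.42) among the lower.

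The cyclin-dependent kinase inhibitor Cdkn1a was higher in rod-, cone-, bipolar-, amacrine-, Müller glia-, neurogenic progenitor- and progenitor-like cells and in cluster 3, and was not called in ganglion-like (1.24-fold, 1.12 to 1.37) and astrocyte-like cells (2 against 13 UMIs). Over all kept cells it stood at 28.0 CPM in the control library and 117 in the Mettl14-cKO library (1373 against 5782 UMIs; 4.19-fold, 3.95 to 4.44). Of 17 p53 targets over all cells 6 were higher and 3 lower (median 0.15, percentile 91.7), with Phlda3 (1.61) and Aen (1.36) higher and Perp (-0.72) and Plk2 (-0.69) lower. The integrated stress and unfolded protein response had 5 of 20 higher and 4 lower (median -0.083, percentile 28.4), Sesn2 (0.64) against Atf4 (-0.63). Interferon response genes had 6 of 17 higher and 3 lower (median 0.082, percentile 65.1), Eif2ak2 (0.96) against Stat2 (-0.37). Reactive glia genes had 4 of 15 higher and 2 lower (median 0.085, percentile 67.7), Socs3 (1.26) against C3 (-1.69). Immediate early genes had 7 of 18 lower and 3 higher (median -0.18, percentile 7.85), Nr4a1 (-0.93) and Ier2 (-0.76) among the lower. Hypoxia and glycolysis genes had 9 of 19 lower and 1, Adm (1.58), higher (median -0.31, percentile 0.130), with Ndrg1 (-0.94) and Aldoa (-0.72) lower.

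**Figure D3:**
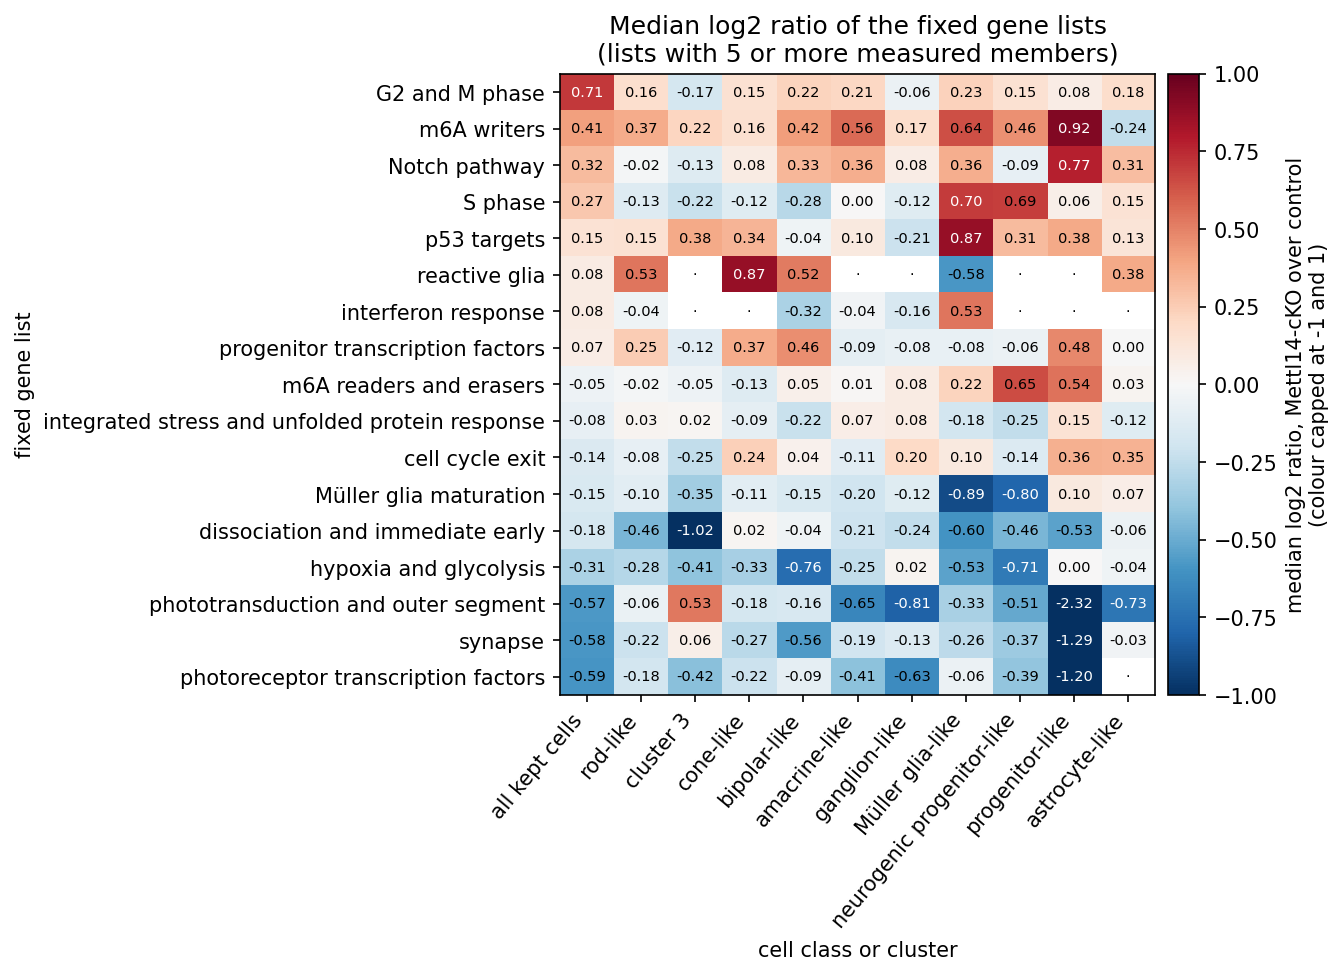
Median log2 ratio (Mettl14-cKO over control) of each fixed gene list with at least 5 measured members, by cell class; red is higher and blue lower, and a dot marks lists with fewer members. Müller glia maturation stands at -0.89 in Müller glia-like cells, and phototransduction at 0.53 in cluster 3 and -0.57 over all kept cells.

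Among all kept cells the gene with the highest ratio was Pmch, which encodes melanin-concentrating hormone (3 against 286 UMIs, log2 6.57, interval 5.00 to 8.85). It was found in 0.0189% of control and 0.366% of Mettl14-cKO cells, and the interval takes UMIs of a cell as independent. Olfr57 (5.36), Aspdh (4.21), the zinc finger genes Zfp992 (3.69), Zfp993 (3.45) and Zfp433 (2.61), Tstd1 (3.11), Col20a1 (2.93), the hormone gene Pyy (2.92), thymidine kinase Tk1 (2.72), the matrix protease Mmp2 (2.69) and Igf2bp1 followed. The lowest genes included several of blood and vessel cells and of pigment epithelium. S100a9, a neutrophil gene, had 382 against 0 UMIs, 128-fold lower at the floor of 3 counts (interval of the ratio up to 0.00965). All of its UMIs came from 3 control cells (0.0284%), and the interval takes UMIs of a cell as independent. S100a8 stood at -5.08 but at 1.15 with the stricter cell filter. Pmel (-4.13) and Ttr (-3.33) are pigment epithelium genes, and Cldn5 (-3.08) and Cd93 (-3.27) endothelial ones; Cd93 turned to 0.34 with the looser filter. Others were Xlr3b (-3.94), Slc38a5 (-3.72), Dynlrb2 (-3.49), Otor (-3.09), Bmp3 (-2.99) and Lhx3 (-2.85). Abcd4, from the 1 list fixed beforehand that is not described here, stood at 11.7 against 40.3 CPM (3.46-fold, 3.15 to 3.80).

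Cells from outside the neural retina were few. Astrocyte-like cells were 0.625% and 0.932%, microglia-like cells 0.417% and 0.632%, pericyte-like cells 0.388% and 0.266%, and pigment epithelium-like cells 26 and 2 cells (0.246% and 0.0166%). Endothelial markers, which formed no cluster, had 6 of 8 lower and 1 higher, with a median of -1.37. Transcripts of other classes were found in both libraries. At 1500 UMIs Gngt1 was found in 24.2% of Müller glia-like, 24.5% of amacrine-like and 18.2% of astrocyte-like cells of the control library, and in 11.5%, 11.6% and 10.0% of those of the Mettl14-cKO library. The unthinned shares were 45.3%, 50.1% and 51.5% against 24.2%, 22.0% and 29.5%. Gngt1 was also lower in rod-like cells, and other genes, chosen after their values were seen, differed less or the other way. Pdc, a rod gene, was found in 24.3%, 24.1% and 15.2% of the same classes of the control and 21.2%, 18.4% and 13.6% of the Mettl14-cKO library (unthinned 40.8%, 45.7% and 45.5% against 37.8%, 32.6% and 42.9%). In rod-like cells the glial genes Glul and Apoe were found in 4.76% and 14.3% of control and 4.64% and 35.5% of Mettl14-cKO cells (unthinned 9.33% and 24.2% against 11.1% and 47.7%). Mitochondrial transcripts made up 3.90% of UMIs in control and 3.00% in Mettl14-cKO cells, with 9 of 13 mitochondrial genes lower (median -0.34); ribosomal protein transcripts made up 10.1% and 12.1%, with 30 of 83 genes higher and 1 lower (median 0.22). Of X-inactivation and Y-linked genes 2 were measured and neither was higher or lower. Xist stood at 1416 and 1456 CPM, while Ddx3y, Eif2s3y and Kdm5d had 0 UMIs and Uty 1 UMI in each library.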

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

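The size limits that picked the genes below were set after the data had been seen, and none of the differences between classes was tested. The genes belong to the fixed lists and stood at least 2-fold higher in 1 named class and at least 2-fold lower in another, each with intervals that did not overlap, which with 1 library per genotype covers counting error only.

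Hes5, a Notch effector, stood at a log2 ratio of 1.59 in progenitor-like cells (30 against 268 UMIs) and at -1.25 in neurogenic progenitor-like cells (106 against 116 UMIs), a difference of 2.84. Gnao1, which encodes a G protein of the ON bipolar response, stood at 1.17 in astrocyte-like cells (24 against 80 UMIs). In bipolar-like cells, whose clusters differed in mix between the libraries, it stood at -1.28 (6069 against 2804 UMIs), a difference of 2.45. Trf, which encodes transferrin, stood at 1.08 in astrocyte-like cells (49 against 153 UMIs) and at -1.35 in Müller glia-like cells (71 against 39 UMIs), a difference of 2.43. Rp1 stood at 1.02 in bipolar-like cells (1037 against 2349 UMIs) and at -1.20 in progenitor-like cells (113 against 146 UMIs), a difference of 2.21; the control progenitor-like cells carried rod transcripts, as their share with Gngt1 shows.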

How the results depend on the processing

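All settings below were planned before the data were examined except size factors for the gene lists. Mettl14 kept its direction and stayed inside its counting interval in all 71 alternative values over 9 results. Of 516 values for 53 gene lists, 512 stayed inside the interval of the median and all 516 kept its direction where that interval excludes 0; size factors moved the ratios of a class by at most 0.077 (log2, cone-like cells). Of 3757 values for 386 named genes, 3322 stayed inside the interval, 425 moved outside it and 10 turned a called direction. The cause was not tested for any value below. Depth limits the small classes most, where a class of few cells leaves ratios to genes with many UMIs.

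Shares, as the ratio Mettl14-cKO over control, moved for rod-like cells from 0.473 to 0.551 with the looser and 0.566 with the stricter cell filter, 0.624 with doublets kept, 0.668 and 0.842 at Leiden resolutions 0.5 and 2, and 0.709 with libraries clustered alone. The bipolar-like ratio of 1.19 went to 1.07 with the looser filter and turned to 0.947 with the stricter one, which marked 18.4% of Mettl14-cKO cells as doublets. With the stricter filter the amacrine-like ratio of 1.43 went to 1.09 and the neurogenic progenitor-like ratio of 2.21 to 3.21; the latter was 2.81 with libraries clustered alone. Clustered alone, the control library had no progenitor-like or pericyte-like cluster and the Mettl14-cKO library no pigment epithelium-like one, so these gave no ratio.

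Among lists, the S phase median in neurogenic progenitor-like cells was 0.013 with at least 100 UMIs per gene, and the Müller glia maturation median in the same class was -0.98 and -1.30 at Leiden resolutions 0.5 and 2 and -1.16 without cell cycle genes. The ratio of shares of Müller glia-like cells called S or G2/M was 7.48 when replaced by the share with 2 of 5 proliferation genes, which moves the first and turns the second; the same replacement gave no value in neurogenic progenitor-like cells, with 0 control cells. Clusters 3 and 8 were not followed in other clusterings.

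Of the genes, S100a8 over all kept cells turned to 1.15 with the stricter filter, Cd93 to 0.34 with the looser filter and 0.36 with doublets kept, and Ifitm3 to 0.25 and 0.29 in the same settings and 0.047 as a mean of per-cell counts. With cells thinned to 1500 UMIs, Bst2 over all kept cells turned to -0.084 and Ei24 in cone-like cells to 0.49. Grm6 in amacrine-like cells turned to 0.19 with doublets kept. Guca1b in rod-like cells turned to -0.088 at Leiden resolution 2.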

Other observations

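The test on Abcd4, those on depth and on rod RNA in Müller glia-like cells, and the bound for rod-like maturity were chosen after the results were seen; all other tests here had their outcome bounds written before the tests were run. Each pattern was found and tested on the same 2 libraries, so the readings below are hypotheses.

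Across classes, genes with 1 exon stood higher in the Mettl14-cKO library than genes with several exons. In rod-like cells the median log2 ratio was 0.34 for the 309 genes with 1 exon, 0.35 for 474 genes with 2 exons and -0.20 for 2349 genes with 17 or more. In amacrine-like cells it was 0.32, 0.29 and 0.077 for the same groups, and it did not fall further between 5 to 8 exons (0.0018) and 9 to 16 (0.016). The median difference between 1-exon genes and all others was 0.41 in rod-like, 0.45 in bipolar-like, 0.27 in amacrine-like, 0.24 in ganglion-like and 0.42 in Müller glia-like cells.

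Several readings of this exon pattern were weighed. Matching on transcript length and level left a difference of 0.40 in Müller glia-like cells over 267 one-exon genes, which argues against length or level as the whole cause. Astrocyte-like cells, which do not descend from retinal progenitors, showed a difference of -0.037 over 115 genes. For these genes that argues against a property of the whole library such as priming from genomic DNA. They were fewer and shorter (median length 1831) than those in Müller glia-like cells (2482), where the difference was not computed on the same genes. Whether astrocyte-like cells kept Mettl14 is not known, so their value does not bear on its loss. The lowest difference over rod-, bipolar-, amacrine- and Müller glia-like cells was 0.27, which met the bound set for loss of Mettl14 in the retinal lineage. Ganglion-like cells (0.24) were not part of that bound. Meeting it does not tell loss of Mettl14 apart from other causes shared by these classes, such as the Cre transgene that the control lacked. That m6A is depleted near exon junctions, so that genes with few exons carry more of it, is known background; no m6A was measured here.

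Müller glia-like cells of both libraries fell in different clusters, and many of their genes stood at least 2-fold apart. A difference between the libraries that moved all classes alike would move these genes in astrocyte-like cells too. Their median log2 ratio there, signed by the direction in Müller glia-like cells, was 0.18 over the 308 of 676 genes measured. It was 1.29 in Müller glia-like cells, where the genes were picked for differences of at least 2-fold, which raises that value. In astrocyte-like cells 62.0% of the measured genes went the same way. A difference in handling that acts on some classes only was not tested. Depth per cell, with medians of 3632 and 3312 UMIs, would set shallow and deep cells of the same library apart in these genes, but the signed median of cells below over cells above the median depth of each library was 0.022 over 676 genes (interval -0.00016 to 0.043), against 1.33 between the libraries. Free rod RNA is argued against as the main source as well. Fixed rod markers reached at most 3.96% of their rod-like level in control and 3.62% in Mettl14-cKO Müller glia-like cells, and at these fractions rod RNA supplies at least 50% of the higher level for 0.740% of the genes (0.241 to 1.72%). Variation between animals stays open, since each genotype has 1 library.

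Abcd4 was higher in the Mettl14-cKO library in each class with at least 30 UMIs, and in astrocyte-like cells by 11.02-fold (6.30 to 21.0; 13 against 212 UMIs). Loss of Mettl14 in the retinal lineage cannot be told apart from other causes of this ratio, because 11 against 8 UMIs of Mettl14 do not show whether the astrocyte-like cells kept it.

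A further hypothesis is that Müller glia- and rod-like cells of the Mettl14-cKO library may be less mature. Across 6380 genes, the log2 ratio in Müller glia-like cells correlated with the control ratio of neurogenic progenitor- and progenitor-like cells together over Müller glia-like cells at Spearman's rho 0.285 (Pearson's r 0.316), with different control cells behind each ratio. The ratio in rod-like cells correlated with the control ratio of cluster 3 over rod-like cells at rho 0.274 (r 0.337) over 7465 genes. The first value is in line with a shift of Müller glia-like cells toward the less mature state, but genes are not independent replicates and most of the variation across genes lies outside this axis. The second shows a likeness to cluster 3 only: whether rod-like cells are less mature stays open, since cluster 3 met no class and phototransduction genes in rod-like cells went both ways (median -0.064).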
